A study of Mus musculus with 8 samples.

How the data were processed

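The series measured polyadenylated RNA of the LGE dissected from E18.5 mouse embryos, with 4 control libraries (floxed Isl1 alleles without Cre) and 4 libraries of Isl1 conditional knockouts (floxed Isl1 alleles with Dlx1-cre), per the labels. Per the labels' protocols, embryos were genotyped from tail tissue, 1 ug of total RNA entered poly(A) selection, libraries were made with a directional kit, and single reads of 85 bp were sequenced. The labels call the samples separate embryos of littermate groups in quadruplicate but give neither litter nor sex. Groups and replicate numbers were taken from the sample labels.

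Per the submitters' processing notes, the authors used STAR, featureCounts and edgeR on build mm10, with no versions given. The counting options, including strand, are not given in the sources used here. The deposited file lists 15705 genes. The authors' columns named as raw hold a score rather than read counts, because the values were scaled and adjusted before they were rounded. Their upper quartiles lay between 1624 and 1635 in the 8 libraries, a range of 0.677%. In the natural log of the deposited value plus 1, for the 5711 genes with a mean above 1000, 1 direction of the 8 libraries had almost no variation. Its singular value was 0.000241, against 0.0433 for the next smallest and 0.187 for the largest. Its weights summed to 0 within each genotype group. This is the trace of 1 unwanted factor removed from every gene, a step read from the values and not stated in the sources used here. It leaves the difference of the group means on the log scale as it was, and it reduces the spread between replicates, so SDs and SEs are too small to a degree. Read counts and depth cannot be recovered from these values, no count model was fitted, and no counting interval is given. The deposited RPKM columns are these values divided by their sum and by gene length, per the file headers and the values. The authors' deposited log2 fold changes, p-values and adjusted p-values were used as an alternative. The column name gives the fold change as control against knockout, but its sign is that of knockout over control.

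The fixed plan named a count test if the file held counts and limma if it held normalized values, and the second applied. Values were transformed to log2(value + 1), genes with a value of at least 1 in 4 or more libraries were kept (15698 genes, with 7 left out), and the groups were compared with limma 3.58.1 (moderated test with a mean trend) in R 4.3.3, with the data.table package (version 1.17.8). The p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The use of the rounded columns in place of RPKM was decided after the file was seen. Errors are SE of the fitted log2 fold change, or SD over 4 libraries. Exact permutation tests enumerated the 70 assignments of the 8 libraries, two-sided. They take the libraries as exchangeable, which the removed factor breaks because it was orthogonal to the real groups alone. Their p-values may therefore be too small.

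Before the data were examined, 25 gene lists with 284 entries were fixed, covering striatal neuron types, compartments, progenitors, signalling pathways and other cells that the dissection could hold. Some genes are in more than 1 list, such as Plxnd1, Gbx2 and Nr4a1. Lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, each adjusted over 24 lists. Camera compares a list with the other genes, and fry asks whether the genes of a list move on balance in 1 direction. The named genes were also fixed by a rule. They are Isl1; the 12 largest rises and 12 largest falls among genes that passed, had a mean of at least 1 when the library sum is scaled to 1000000, and no overlap between groups, leaving out sex-linked genes and gene models without a proper symbol; members of the striatonigral, striatopallidal and cholinergic lists; and up to 4 members with the smallest p of every other list. Genes named outside this rule include Sst, Xist, Slc4a1 and Efnb3, besides those named for a locus, a run of neighbours or a later test. Some genes that the rule names are not reported here but stayed in the list tests, and the comparison of Dlx-expressing cells was made again with 1 gene fewer after its first result was seen.

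Coordinates are those of the GENCODE annotation of GRCm38, the assembly that mm10 denotes, in which 15356 of the 15705 symbols (97.8%) were found. Of the listed genes, 47 hold values identical to another gene, 4 of them among the called genes.

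The procedure was tested on simulated data with 15698 genes, of which 200 were changed, in 10 simulations of this comparison. With the leading residual direction of the simulated values removed from every gene, limma recovered 74.8% of changes of 0.5 on the log2 scale. It recovered 95% of those of 1, 99.2% of those of 2 and 100% of those of 3. False calls then made up 12.3% of the calls, against 4.63% with nothing removed and 4.29% with the removed direction charged to the model as a covariate. The simulated noise was independent between genes, so the direction removed was no shared factor of the kind the deposited values may have held. The share of false calls among the 1045 genes may therefore be higher than the nominal level, to a degree this simulation does not give. Camera and fry each recovered 20 of 20 simulated lists of 12 genes shifted by 0.6, and called none of 180 lists without a shift. In that simulation the genes varied independently and no direction was removed. The estimated correlation between genes of the real lists reached 0.64 (erythroid), so these counts give no false call rate for the real lists.

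Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at a mean of 1 per 1000000, scaling by the library total or by the median of ratios, the replicate number as a block, Xist as a covariate, a test against a log2 fold change of 0.5, the authors' deposited table, and leaving out each library in turn. Count models, which need read counts, were not run. Added after the data were seen were the removed direction as a covariate, the RPKM columns, leaving out the pair of libraries lowest in pallial markers, and restriction to the libraries with Y-linked and without Xist transcripts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.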

Results

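Poly(A) RNA was sequenced from the lateral ganglionic eminence (LGE), the embryonic structure that gives rise to the striatal projection neurons, of E18.5 mouse embryos. Embryos with 2 floxed alleles of Isl1 and Dlx1-cre, in which Isl1 is deleted where the Dlx1-driven recombinase is active, were compared with littermates carrying the floxed alleles without the recombinase. Isl1 is a LIM-homeodomain transcription factor of ventral forebrain neurons. There were 4 libraries labelled conditional knockout (cKO) and 4 labelled control, and the comparison asks which transcripts of the LGE depend on Isl1. Because Dlx1-cre was present in the cKO alone, the presence of Cre and the deletion of Isl1 could not be separated. The values are adjusted read values per gene and library, rounded to whole numbers. They summed to between 23732455 and 24456923 per library, but these sums follow from the scaling, and the sequencing depth is unknown. The 10 most abundant genes took between 3.16% and 3.73% of each sum.

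Isl1 itself (chromosome 13, 116298281 to 116309689, minus strand, GRCm38) was higher in the libraries labelled cKO. The control libraries held Isl1 values of 3777, 3692, 4186 and 3517, with a mean of 3793 ± 283 (SD, n = 4). The libraries labelled cKO held 4930, 5377, 5618 and 5971, with a mean of 5474 ± 437 (SD, n = 4). The log2 fold change was 0.53 ± 0.06 (SE), or 1.44-fold between the means, with a limma adjusted p of 0.000338. An exact two-sided permutation test of the 8 values gave p = 0.0286, the smallest that 4 against 4 libraries can give. Because the removed factor reduced the spread within the groups, this p may be too small. The value counts reads over the whole gene, and the part that Cre removes is not given in the sources used here. It therefore does not check the genotype labels, and it goes against a simple loss of the transcript. In what follows, control and cKO mean the libraries so labelled, and every direction rests on those labels.

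**Figure D1:**
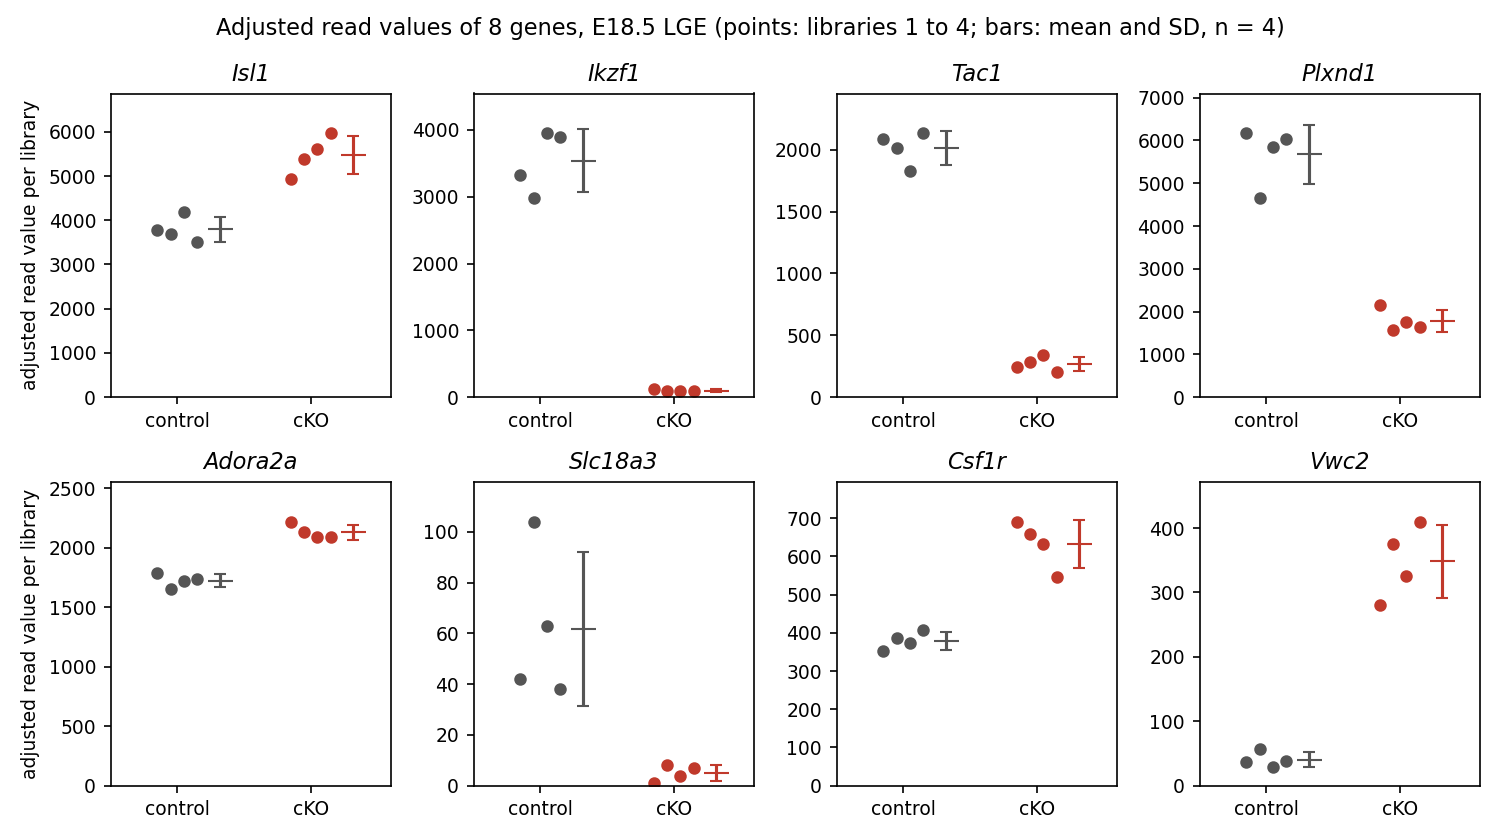
Adjusted read values (vertical axes, linear and starting at 0) of 8 genes in each of the 4 control (grey) and 4 cKO (red) libraries, with the group mean and SD. Isl1 lay between 3517 and 4186 in the controls and between 4930 and 5971 in the libraries labelled cKO, while Ikzf1, Tac1, Plxnd1 and Slc18a3 were lower in all 4 cKO libraries than in any control.

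In the cKO, 594 genes fell and 451 rose among 15698 tested (limma, Benjamini-Hochberg adjusted p under 0.05), 6.66% of the genes. Of these 1045 genes, 134 fell and 76 rose by a log2 fold change of at least 1. The 4 cKO values did not overlap the 4 control values in 12.7% of all tested genes, where chance gives 2.86% if libraries are exchangeable. The removed factor was orthogonal to the real groups alone and reduced the spread within them. The libraries are therefore not exchangeable, and the 12.7% may be inflated. The fall of Ikzf1, a zinc finger transcription factor, was among the largest. Its mean dropped from 3537 ± 469 to 99 ± 18.2 (SD, n = 4), a log2 fold change of -5.15 ± 0.12 (SE). The sodium channel gene Scn10a, with a log2 fold change of -5.36 ± 0.38, went from a mean of 64.3 to 0.75. Other transcripts among the 12 largest falls were Brs3, a bombesin receptor (-3.71 ± 0.12), the organic cation transporter Slc22a3 (-3.33 ± 0.15), the collagen gene Col6a1 (-3.19 ± 0.16), Glt8d2 (-3.07 ± 0.54), Insrr (-2.97 ± 0.26) and the orphan receptor Gpr151 (-2.83 ± 0.24). Among the 12 largest rises, Vwc2 increased from 40.3 ± 11.9 to 348 ± 56.6, a log2 fold change of 3.11 ± 0.19. Bhlhe22, a basic helix-loop-helix transcription factor, rose by 2.61 ± 0.39, the potassium channel gene Kcnj5 by 2.27 ± 0.14 and Prr15 by 1.87 ± 0.24. Cadps2 rose by 1.87 ± 0.20, the muscarinic receptor gene Chrm3 by 1.69 ± 0.19, the receptor phosphatase gene Ptprk by 1.68 ± 0.11, Klhl1 by 1.63 ± 0.10 and Cfap161 by 1.44 ± 0.16. The rule that picked these genes required that the groups did not overlap. Among those given in this paragraph, the largest limma adjusted p was 0.00461, for Glt8d2. Cd84, another of the 12 largest rises, was at 0.00532. The authors' deposited table held 1028 genes at an adjusted p under 0.05, 846 of them shared with the 1045 and all 846 with the same direction. The count fell to 749 genes, 290 risen and 459 fallen, when the direction of variation missing from the values was charged to the model, and to 659 without control replicate 4. A test against a log2 fold change of 0.5 left 122 genes, Isl1 not among them.

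Markers of striatonigral (direct pathway) neurons fell, and those of striatopallidal (indirect pathway) neurons did not. Of 11 striatonigral list members, 6 fell and none rose, both over the whole set of genes and adjusted over the list alone. Tac1, the substance P precursor, dropped from 2015 ± 137 to 268 ± 58.1 (log2 fold change -2.93 ± 0.13). Slc35d3 fell by 2.05 ± 0.09 on the log2 scale, the dynorphin precursor Pdyn fell by 1.77 ± 0.08, and the semaphorin receptor gene Plxnd1 fell by 1.68 ± 0.10. The muscarinic receptor gene Chrm4 fell by 1.05 ± 0.15 and Zfp521 by a log2 fold change of -0.33 ± 0.07. The dopamine receptor gene Drd1, which defines these neurons, had a log2 fold change of -0.20 ± 0.08 (adjusted p = 0.217), Ebf1 of -0.01 ± 0.07 and Eya1 of -0.22 ± 0.18, none of which passed the test. Drd1 passed without control replicate 3, at a log2 fold change of -0.27 (adjusted p = 0.0421). In the gene set test camera, the striatonigral list was lower with an adjusted p of 4.71e-09, and the adjusted p was 0.0218 with an estimated correlation.

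Of 11 striatopallidal list members, 2 rose, 4 rose adjusted over the list alone, and none fell. Adora2a, the adenosine receptor gene of these neurons, went from 1724 ± 55.9 to 2132 ± 62.5, a log2 fold change of 0.31 ± 0.04 (adjusted p = 0.000477). Drd2 rose by 0.20 ± 0.05, with an adjusted p of 0.0367 that did not hold when the missing direction was charged to the model (adjusted p = 0.079) or with the median-of-ratios scaling (adjusted p = 0.0611). Its call was also lost without control replicate 2 or 4 and without any 1 of the 4 cKO libraries, with adjusted p between 0.0602 and 0.108. Six3, with a log2 fold change of 0.20 ± 0.06 (adjusted p = 0.0589), passed without control replicate 2 (adjusted p = 0.0461), with either other scaling (0.0424 and 0.0468) and with the replicate block (0.0367), while Sp9 was at 0.05 ± 0.05 and the enkephalin precursor Penk at 0.02 ± 0.10. The list was higher in camera with an adjusted p of 0.00116, and the adjusted p was 0.0567 with an estimated correlation.

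**Figure D2:**
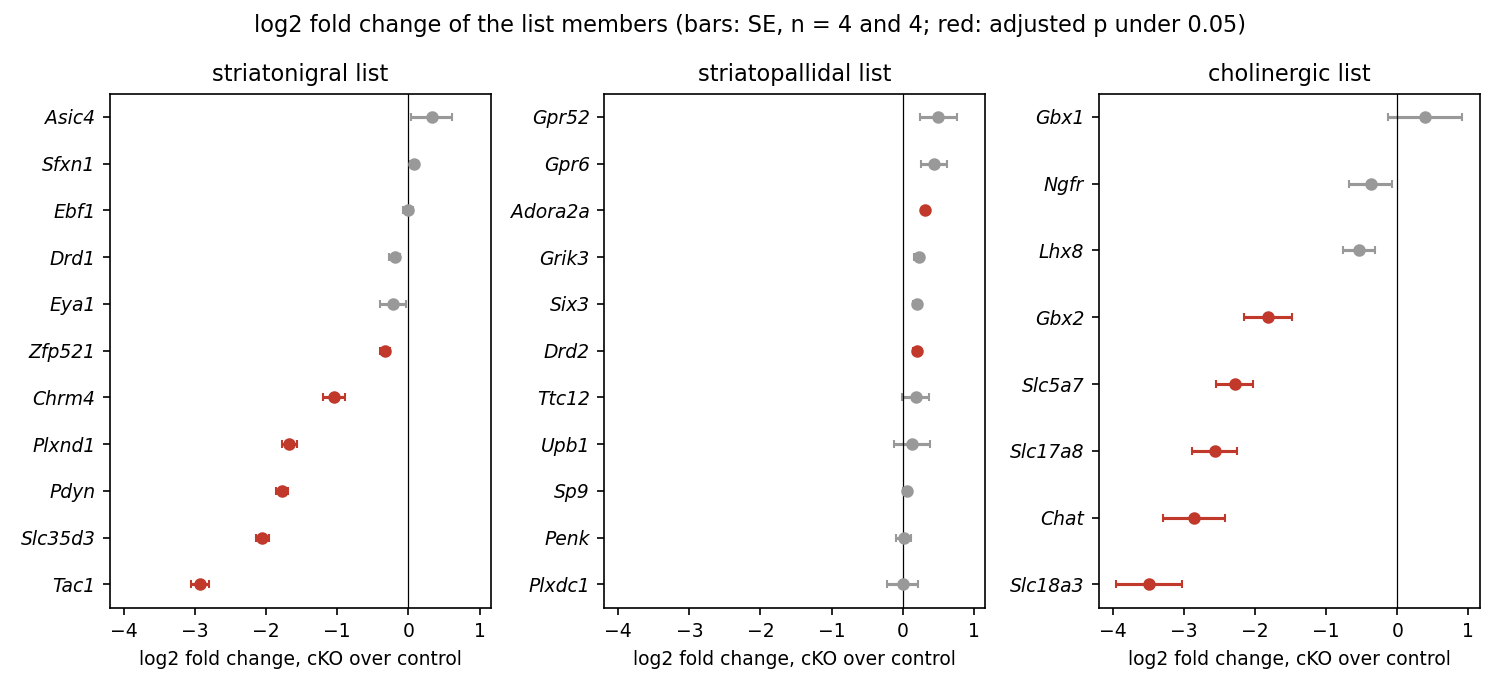
The log2 fold change of cKO over control (horizontal axes) of members of the striatonigral, striatopallidal and cholinergic lists, with SE (4 against 4 libraries) and members past the adjusted p of 0.05 in red. Of the members shown, the striatonigral ones that passed lay between -2.93 and -0.33. Those shown that passed in the striatopallidal list lay at 0.20 and 0.31, and in the cholinergic list between -3.48 and -1.81. Not every cholinergic list member is shown.

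Genes shared by both kinds of striatal projection neuron fell in part. Of 18 members, 9 fell and 1 rose, and adjusted over the list alone 9 fell and 2 rose. Besides Ikzf1, Arpp21 decreased from 4627 ± 336 to 2064 ± 291 (log2 fold change -1.17 ± 0.09). Meis2, a homeodomain transcription factor, rose by 0.34 ± 0.05. The camera adjusted p was 4.32e-07, and 0.0567 with an estimated correlation. Of 5 striosome (patch compartment) genes, 3 fell, namely the opioid receptor gene Oprm1 by a log2 fold change of -1.04 ± 0.19, Nr4a1 by -0.74 ± 0.11 and Bach2 by -0.23 ± 0.04, with 4 falling adjusted over the list alone (camera adjusted p = 4.44e-05, and adjusted p = 0.0567 with an estimated correlation). Of 5 genes of the surrounding matrix, Gda fell by a log2 fold change of -1.24 ± 0.10 and the calcium-binding protein gene Calb1 by -0.73 ± 0.05, while Id4 rose by 0.36 ± 0.05. Adjusted over the list alone, 2 matrix genes fell and 2 rose, and the list did not pass camera (adjusted p = 0.167) but was lower in the set test fry (adjusted p = 0.000993).

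Genes of cholinergic neurons were among the most reduced. Of 9 members, 6 fell, 7 adjusted over the list alone, and none rose. The vesicular acetylcholine transporter gene Slc18a3 was at 61.8 ± 30.2 in the controls and 5 ± 3.16 in the cKO (-3.48 ± 0.47). Chat, which encodes the enzyme of acetylcholine synthesis, had a log2 fold change of -2.85 ± 0.43, from low control values of 14.5 ± 5 to 1.25 ± 0.957. The vesicular glutamate transporter gene Slc17a8 fell by 2.57 ± 0.32 on the log2 scale, the choline transporter gene Slc5a7 fell by 2.29 ± 0.26, and the homeobox gene Gbx2 fell by 1.81 ± 0.34. The transcription factor gene Lhx8 had a log2 fold change of -0.54 ± 0.23 (adjusted p = 0.224), and passed without cKO replicate 4 (-0.76, adjusted p = 0.0428). The list was lower in camera with an adjusted p of 1.12e-08, and the adjusted p was 0.0567 with an estimated correlation. Among 12 markers of interneurons from the medial ganglionic eminence, 3 fell and 1 rose, and 4 and 2 adjusted over the list alone. Neuropeptide Y (Npy) fell by 0.71 ± 0.13 on the log2 scale, the chemokine receptor gene Cxcr4 fell by 0.44 ± 0.08, the nitric oxide synthase gene Nos1 fell by 0.59 ± 0.14, and Maf rose by 0.31 ± 0.05. The Nos1 call was lost in 5 of the 8 fits that left out 1 library (without control replicate 1, 2 or 4, or cKO replicate 2 or 3), with adjusted p up to 0.0818. Sst, which the rule for named genes did not pick, had a log2 fold change of -0.53 (adjusted p = 0.056). It passed without control replicate 3 (adjusted p = 0.0422) or cKO replicate 4 (adjusted p = 0.0441), and with median-of-ratios scaling (0.0477). Sst also passed with the replicate block (0.0208), in the authors' table (0.0247) and without the libraries lowest in pallial markers (0.0343). The interneuron list did not pass camera (adjusted p = 0.413).

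Some components of retinoid signalling, neuropeptides and activity-regulated genes also fell. Of 13 retinoid genes, 6 fell and none rose, with 6 and 2 adjusted over the list alone. Stra6, a retinol uptake receptor, went from 558 ± 30.9 to 261 ± 3.79 (log2 fold change -1.09 ± 0.06), the retinoic acid binding protein gene Crabp1 fell by 1.07 ± 0.08 on the log2 scale, and the receptor gene Rxrg fell by 0.50 ± 0.07. The camera adjusted p was 0.000252, and 0.131 with an estimated correlation. Of 11 neuropeptide genes, 4 fell, which were Tac1, Pdyn, Npy and Pnoc (-1.28 ± 0.21), with 5 falling and 1 rising adjusted over the list alone (camera adjusted p = 4.44e-05, and adjusted p = 0.133 with an estimated correlation). Of 12 immediate early genes, 6 fell, 8 adjusted over the list alone, and none rose. Egr1 dropped from 502.5 ± 34.1 to 274 ± 47.2 (log2 fold change -0.89 ± 0.11), Arc had a log2 fold change of -0.82 ± 0.13, and Egr4 of -1.33 ± 0.22 from low values. Their camera adjusted p was 8.69e-07, and 0.0567 with an estimated correlation. Of 26 axon guidance genes, 5 fell, among them Plxnd1, Sema6a (-0.35 ± 0.06), Robo2 (-0.25 ± 0.05) and Robo1 (-0.23 ± 0.05), and 1 rose, with 5 and 4 adjusted over the list alone. The Robo1 call was lost without control replicate 3 or 4 or cKO replicate 2 or 3 (adjusted p between 0.06 and 0.0662). The riser was Efnb3, named here after its value was seen (0.17, adjusted p = 0.0498), whose call was lost in 6 of the 8 fits that left out 1 library. The axon guidance list did not pass camera (adjusted p = 0.897).

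None of 20 proliferation genes passed the test, over the whole set of genes or adjusted over the list alone, and the camera adjusted p was 0.413. Top2a had a log2 fold change of 0.06 ± 0.06 and Ccnb1 of 0.10 ± 0.05. None of 8 genes of dorsal LGE olfactory interneurons passed, and 1 fell adjusted over the list alone (camera adjusted p = 0.715). Its member Prokr2 (-0.21, adjusted p = 0.0664) passed with the replicate block (0.0227) and without control replicate 2 (0.0499) or cKO replicate 3 (0.0371). Of 11 genes of the p53 response 1 fell, Cdkn1a, with a log2 fold change of -0.52 ± 0.11, a call lost without control replicate 4 (adjusted p = 0.0549) or cKO replicate 3 (adjusted p = 0.0575). Adjusted over the list alone, 1 p53 gene fell and 1 rose (camera adjusted p = 0.561). Of 12 ventricular progenitor genes, 2 rose, Dlx1 and Dlx2, with 2 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.561).

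The rise of Dlx1 and Dlx2 was shared by their neighbours on chromosome 2. Dlx1 (71528113 to 71533981, plus strand, GRCm38) went from 9977 ± 599.7 to 15385 ± 564.8, a log2 fold change of 0.63 ± 0.05 (adjusted p = 8.51e-06). Dlx2 (71543408 to 71546754, minus strand) rose by 0.31 ± 0.06 (adjusted p = 0.00731). Dlx1as, an antisense transcript (71516454 to 71537891, minus strand), rose by 1.24 ± 0.07, from a mean of 4351 to 10232, and Metap1d (71453276 to 71525194, plus strand), which encodes a methionine aminopeptidase, rose by 1.02 ± 0.06. Both were picked out after their values were seen. The nearest tested genes on either side did not pass, with adjusted p of 0.21 for Hat1 and 0.663 for Itga6. Dlx1as overlaps Metap1d and Dlx1 on the opposite strand. The library kit keeps strand, but whether reads were counted by strand is not given in the sources used here, so the values of these 3 genes are uncertain.

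**Figure D3:**
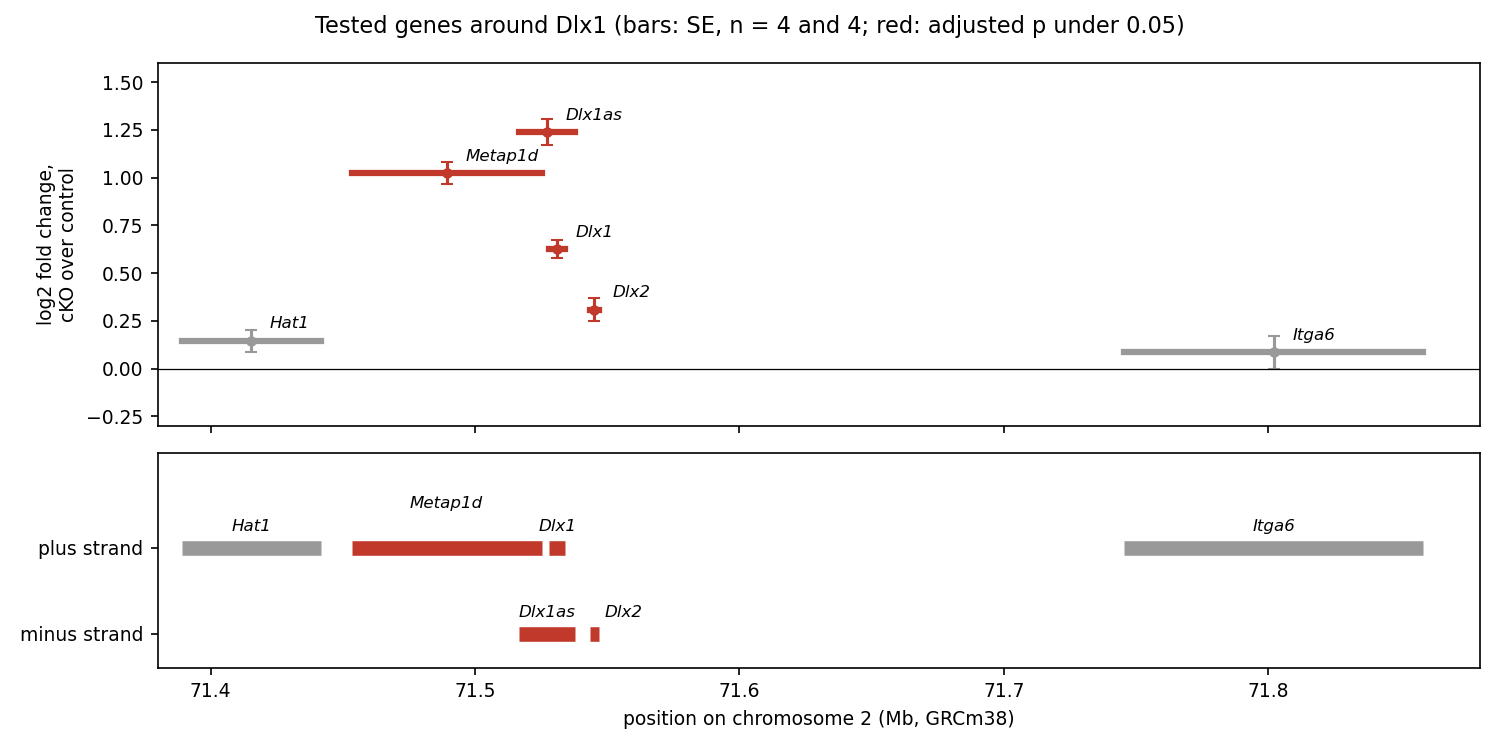
Upper panel, log2 fold change of cKO over control with SE (4 against 4 libraries) of the tested genes around Dlx1, drawn over their annotated extent on chromosome 2 (Mb, GRCm38), and lower panel, the same genes by strand. Metap1d, Dlx1as, Dlx1 and Dlx2 (red, adjusted p under 0.05) rose by 1.02, 1.24, 0.63 and 0.31, and Hat1 and Itga6 (grey) did not pass the test.

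Among markers of other cells that the dissection could hold, those of microglia rose. Of 12 microglial genes, 10 rose, 11 adjusted over the list alone, and none fell. Trem2, a microglial receptor gene, increased from 32.3 ± 8.81 to 87.8 ± 8.10 (log2 fold change 1.46 ± 0.20), the growth factor receptor gene Csf1r from 380 ± 23.5 to 632 ± 61.7 (0.73 ± 0.08), and the complement genes C1qa and C1qc by 0.91 ± 0.11 and 0.90 ± 0.10. Spp1, which activated microglia also express, rose by 2.44 ± 0.33, and the leukocyte receptor gene Cd84 by 1.43 ± 0.26. The mean log2 value of the microglia list lay between 7.025 and 7.257 in the controls and between 7.74 and 8.084 in the cKO. The camera adjusted p was 1.56e-15, and 0.0567 with an estimated correlation. Of 7 erythroid genes, 3 rose, over the whole set and adjusted over the list alone. These were the haemoglobin genes Hbb-bt (0.51 ± 0.11), Hba-a1 and Hba-a2 (0.39 ± 0.10). The latter pair hold identical values in the file and count as a single measurement. The Hba-a1 call was lost in 5 of the 8 fits that left out 1 library (without control replicate 1 or 4, or cKO replicate 2, 3 or 4), with adjusted p up to 0.133. The Hbb-bt call was lost without cKO replicate 2 (adjusted p = 0.0541) or 4 (adjusted p = 0.0573). The erythroid list had a camera adjusted p of 0.00238, and 0.32 with an estimated correlation. None of 15 vascular genes (camera adjusted p = 0.246), 9 oligodendrocyte lineage genes (0.267) or 7 choroid plexus and ependymal genes (0.572) passed, over the whole set or adjusted over the list alone. Of the choroid plexus and ependymal genes, Ttr passed in the authors' table (adjusted p = 0.000214) and Foxj1 without cKO replicate 3 (0.0488). None of 7 astrocyte genes passed over the whole set and 2 fell adjusted over the list alone (camera adjusted p = 0.396).

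**Figure D4:**
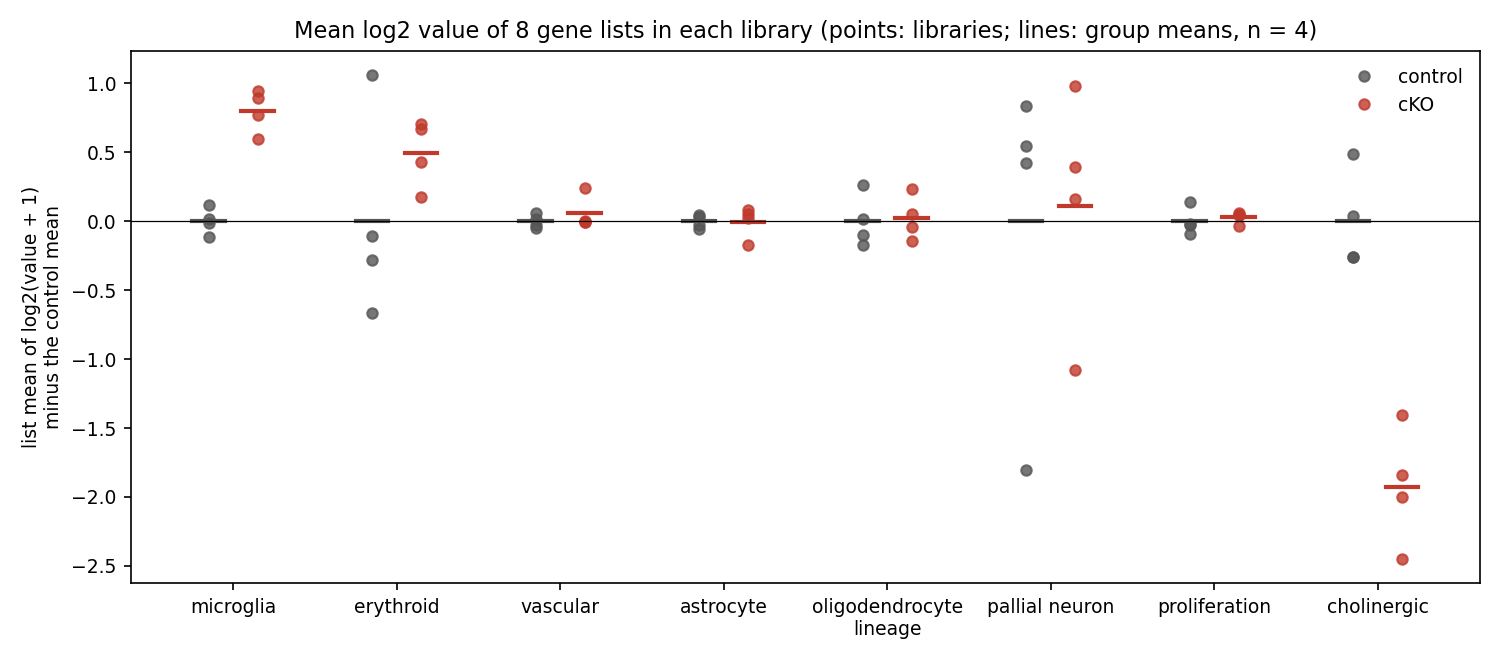
Mean of log2(value + 1) over the members of 8 gene lists, relative to the control mean (vertical axis), in each of the 4 control (grey) and 4 cKO (red) libraries, with lines at the group means. The microglia list means of the cKO libraries lay above those of the controls and the cholinergic ones below, while the pallial neuron list was low in control replicate 3 (3.997) and cKO replicate 4 (4.721).

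Among 12 markers of pallial neurons, which a striatal dissection should largely exclude, 1 rose, Bhlhe22, over the whole set and adjusted over the list alone (camera adjusted p = 0.864). This list varied between libraries, with means of 3.997 in control replicate 3 and 4.721 in cKO replicate 4 against 5.966 to 6.781 in the other 6. Without both of these libraries 610 genes passed. Of 5 thalamic markers, 1 fell, Gbx2, over the whole set and adjusted over the list alone (camera adjusted p = 0.187). The labels give no sex, and sex-linked transcripts differed between embryos. Xist was abundant in control replicates 2 and 4 and cKO replicate 3, at 163643, 30711 and 40998, and between 2 and 45 in the other 5 libraries. Ddx3y, on the Y chromosome, was at 0 and 1 in control replicates 2 and 4 and between 519 and 2219 in the other 6, so that cKO replicate 3 held both transcripts. The unwanted factor was removed from these genes too, so their values need not reflect the levels in the embryos, and sex was not inferred. The Xist covariate and the choice of libraries by these transcripts rest on such adjusted values. None of 6 sex-linked genes passed over the whole set, and 4 rose adjusted over the list alone (camera adjusted p = 0.125). With Xist as a covariate 785 genes passed, and in the 2 control and 3 cKO libraries with Y-linked and without Xist transcripts 411 did.

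How many lists passed depended on the set test and its setting. Camera with its preset correlation called 10 of 24 lists and fry 11, among them the matrix and sex-linked lists (fry adjusted p = 0.0382) but not the erythroid list (0.166). In camera, the striatonigral list was the 1 that held with an estimated correlation. The estimate was 0.017 for this list and -0.032 for the striatopallidal list, against the preset 0.01. Correlation between genes alone therefore does not account for the larger p of either list. With the preset correlation, 10 of the 35 ways to split the 8 libraries into 4 and 4 gave as many lists as the real groups. No member of the list of mitochondrially encoded genes was among the tested genes. For 3 lists that did not pass, the median and the mean log2 fold change of the members had opposite signs, at 0.034 and -0.049 for axon guidance, -0.027 and 0.11 for pallial neurons, and -0.077 and 0.025 for the oligodendrocyte lineage.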

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

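The tests of other splits for the number of genes, of Isl1, of the Dlx1 segment and of the microglial genes were chosen after the results they bear on had been seen, while the splits for the gene lists were not. In each group of 4, the highest or lowest library was compared with the nearest of the others. Of 286 such groups, 16 had a gap above the 95% critical value for 4 samples, where chance gives about 14.3.

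Among control libraries, replicate 3 was low in pallial transcripts, with Emx1 at 1 against 13 to 15, Neurod1 at 5 against 53 to 60 and a pallial list mean of 3.997 against 6.223 to 6.641. It was also low in Eya1, at 79 against 132 to 142. Control replicate 1 was high in Lhx2, at 1004 against 844 to 848.

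Among cKO libraries, replicate 4 was low in Arpp21, at 1629 against 2173 to 2228, high in its vascular list mean, at 8.939 against 8.695 to 8.704, and at 6 for Gpr151 where the others held 5. Replicate 3 was low in Ptprk, at 756 against 874 to 881, and in Rora, at 249 against 291 to 298, and high in Egr4, at 31 against 16 to 17. Replicate 1 was low in Crabp1, at 479 against 576 to 592, and high in Pdgfra, at 720 against 623 to 631. Replicate 2 was high in Lhx2, at 913 against 785 to 801, low in Cspg4, at 278 against 331 to 334, and low in its proliferation list mean, at 10.245 against 10.327 to 10.337.

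The whole-gene value of Isl1 was higher in the libraries labelled cKO. An exchange of the labels of the 2 groups is argued against by the striatonigral list, whose neurons need Isl1 in earlier mouse mutants and whose mean log2 fold change was -0.893 in these libraries. Over 3 other scalings the smallest Isl1 log2 fold change was 0.514, so the choice among these scalings does not account for the higher value. All of them start from values that were already scaled and adjusted. The submitters' own scaling and adjustment therefore could not be tested. Reads from the part of Isl1 outside the deleted segment, with a ratio of 1.44 between the group means, remain open because the file holds no values per exon. No biological explanation of the higher value was tested.

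Dlx1, Dlx1as, Dlx2 and Metap1d, which lie within 93.5 kb, rose in the libraries labelled cKO. For Dlx1, Dlx1as and Metap1d, a higher share of Dlx-expressing cells is argued against as the whole source by smaller changes of other genes of such cells. The median log2 fold change of Dlx5, Dlx6, Dlx6os1, Gad1 and Gad2 was 0.187, and the largest was 0.326, for Dlx6. Since Dlx5, Dlx6 and Dlx6os1 did rise, a higher share may still contribute, and cells with other proportions of these transcripts were not tested. A higher share stays open for Dlx2, which exceeded that median by 0.122, within the spread of those genes. Reads shared between overlapping genes on both strands cannot explain Dlx2 (0.309), which overlaps no annotated gene, and stay open for Dlx1, Dlx1as (a mean increase of 5881) and Metap1d for want of values per strand. Extra copies of the Dlx1 segment in the Cre-bearing genotype stay open as well. Such runs are rare (1 of 15276 others had all 4 risen), but the segment was picked for its rise, so this does not decide. A response of the locus to the loss of Isl1 could give the same pattern, and Cre and the deletion coincide in this design.

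Microglial genes rose in the libraries labelled cKO. A lower share of the main cell type is argued against by the microglia list, which rose by 0.773 on the log2 scale over the mean of the vascular, astrocyte and oligodendrocyte lineage lists (exact p = 0.0286). That p is the smallest these group sizes can give. The microglia list was taken up for a rise already seen, so the p adds no support of its own. For blood left in the tissue, 3 tests were run in turn. The first, fixed before its values were seen, was the median of Siglech, Olfml3, Sall1 and Slc2a5 (0.102). The second, chosen after it, was the rise over haemoglobin transcripts (0.374, exact p = 0.171), and neither decided. The third was chosen after both had failed to decide. With the erythroid list mean as a covariate, which changed the number of genes from 1045 to 719, the median of the microglial genes was 0.87. Of the 12 microglial genes, 10 still passed. The covariate was highest in control replicate 3, at 9.444 against 7.716 to 8.274 in the other controls and 8.559 to 9.091 in the cKO. The fit thus leans on 1 library, and blood left in the tissue stays open. More microglia, or a changed state of them, may lie behind the rise as a hypothesis that was not tested, and bulk tissue does not separate these. Siglech (0.13 ± 0.19), Olfml3 (0.29 ± 0.12) and Slc2a5 (0.03 ± 0.30), which resident microglia express, did not pass. The median of the microglia list was 0.797.

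The number of genes changed was 1045 for the real groups and at most 0 for the other splits, so that 1 of the 35 splits of the 8 libraries gave as many. The removed factor was orthogonal to the real groups alone, so the other splits are not comparable, and this count does not show whether chance can be excluded. Chance could not be excluded for the number of gene lists called by camera, 10 for the real groups and at most 12 for the others, with as many in 10 of the 35 splits.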

How the results depend on the processing

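The removed direction as a covariate, the RPKM columns, the exclusion of the libraries lowest in pallial markers and the restriction to libraries with Y-linked and without Xist transcripts were chosen after the data were seen. Alternatives that need read counts (DESeq2, other count normalizations, recovered reads) were not run, because the values are not counts, and the fold threshold and the authors' table give no camera test. The 6 striatonigral and 6 cholinergic genes that fell were 4 to 7 in every alternative. The number of genes changed was 1045 and ranged from 785 to 1199 over pseudocount, filters, scalings, replicate block and Xist covariate, with 749 for the removed direction and 954 for RPKM. It was 122 in the test against a log2 fold change of 0.5, 610 without the libraries lowest in pallial markers and 411 in the libraries with Y-linked transcripts, where fewer libraries or a stricter hypothesis were used. Leaving out 1 library gave 659 (without control replicate 4) to 959 genes. Against 0.5, Isl1 (0.53) no longer passed (adjusted p = 1, with at most 0.00241 over the fits that left out 1 library) and 1 microglial gene did. The 2 striatopallidal genes that rose became 4 with the replicate block, 0 against 0.5, and 1 with the Xist covariate, the authors' table, the removed direction, RPKM, the libraries lowest in pallial markers left out or those with Y-linked transcripts, and 1 to 2 when 1 library was left out; the cause was not tested. Camera with an estimated correlation called 1 list in place of 10, and leaving out 1 library gave 10 to 13. Of the named genes that did not pass, 10 changed sign. When 1 library was left out, log2 fold changes ranged from -0.052 to 0.068 for Ebf1, -0.055 to 0.13 for Penk, -0.11 to 0.19 for Plxdc1, -0.0024 to 0.28 for Upb1, -0.21 to 1.08 for Neurod1 and -0.063 to 0.74 for Gbx1. Plxdc1 was at 0.11 with the Xist covariate, 0.040 in the authors' table, 0.0049 for RPKM and 0.0077 in the libraries with Y-linked transcripts, where Penk was at -0.056, Upb1 at -0.12, Ngfr at 0.029 and Fezf2 at 0.014. Rora was at -0.0056 with the Xist covariate. Gbx1 was at -0.11 in the authors' table, and without the libraries lowest in pallial markers Ebf1 was at 0.052 and Ttc12 at -0.0078; the cause was not tested. Over the 13 alternatives that left out no single library, the least stable calls passed in 3 (Efnb3), 4 (Drd2), 7 (Hba-a1), 9 (Nos1, Robo1) and 10 (Cdkn1a, Gbx2, Hbb-bt). Other named genes that passed in an alternative alone were Lypd1, Slc1a3, Trp53inp1, Slc1a2 and Grik3 with the replicate block (adjusted p of 0.0331, 0.0327, 0.00804, 0.0363 and 0.0434), Trp53inp1 without control replicate 1 (0.0111), Pdgfra and Aldoc without control replicate 3 (0.0474 and 0.0389), Grik3 without cKO replicate 2 (0.0469), and Lypd1, Aldoc and Grik3 without cKO replicate 3 (0.00536, 0.041 and 0.048). Deviations of same-numbered libraries correlated at 0.23, -0.027, -0.109 and -0.534 across 11723 genes, and control replicate 1 alone correlated best with its own number. The adjusted values thus showed no pairing by replicate number. Since 1 factor had already been removed from them, pairing before that step cannot be excluded. The replicate block gave 1199 genes and 10 lists. Depth is unknown, so no limit of detection can be given for genes with low values.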

Other observations

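The tests of Dlx-related genes below were chosen after the data were seen. Outside the Dlx1 segment, other members of the Dlx family rose by small amounts in the libraries labelled cKO. Dlx5 had a log2 fold change of 0.24 ± 0.04 (limma adjusted p = 0.0017), Dlx6 of 0.33 ± 0.07 (adjusted p = 0.0219) and the antisense transcript Dlx6os1 of 0.19 ± 0.05 (adjusted p = 0.0488). The GABA synthesis genes Gad1 (0.08 ± 0.04, adjusted p = 0.353) and Gad2 (0.04 ± 0.04, adjusted p = 0.657) did not pass. Elsewhere in the genome, the run of 4 neighbouring genes that all rose was Cd53, Kcna3, AI504432 and Kcna2.

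Of the genes expressed by resident microglia that were outside the fixed list, Siglech had a log2 fold change of 0.13 ± 0.19, Olfml3 of 0.29 ± 0.12 and Slc2a5 of 0.03 ± 0.30, and none passed the test. Sall1, with a log2 fold change of 0.08 ± 0.05 and a control mean of 2011, is also expressed by neural progenitors.

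Ttr, a transcript of the choroid plexus, stood at 3462 in control replicate 1 and between 17 and 141 in the other 7 libraries. Slc4a1, an erythrocyte membrane gene, stood at 198 in control replicate 3 and between 3 and 96 in the other 7.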
